A study of Mus musculus with 2 samples.

How the data were processed

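DNase-seq was measured in 2 libraries of kidney tissue from female B6CASTF1/J mice aged 4 days, labelled as biological replicates 1 and 2 of 1 group. The labels name 3 females for each library under 1 donor entry and do not clearly say that the animals differ, so the spread between the libraries may in part be technical. The labels list 2 instrument models for replicate 2, so a difference between the libraries cannot be separated from instruments.

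Each library had its own peak lists, base-wise false discovery rates and footprints on mm10, made from that library's filtered alignment per the notes deposited with the files, with no pooling of libraries. The aligner, the peak caller, the footprint tool and their versions and thresholds are not given in the sources used here. The peak signal is the authors' deposited value in the narrowPeak format, is never negative, and its scale is not stated. Every signal was a whole multiple (within 0.05 of a whole number) of a step of 0.0031 in replicate 1 and 0.00429 in replicate 2. Signals were therefore used to rank and describe peaks within a library, and the depth of each library stays unknown. The deposited file of false discovery rates gives a q-value per base and lists only bases below 0.05. The deposited footprints carry 1 level for the whole list and no p-value each, and the deposited peak files hold no p-value, q-value or summit.

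Each library came with 2 peak lists. The longer list (250423 and 216738 peaks), in which every peak holds a base with a false discovery rate below 0.05, was used throughout. The shorter list (157265 and 133352 peaks), in which every peak holds a base at 0.001 or lower, served as an alternative. This choice was made before overlaps were computed.

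The GRCm38.p6 sequence, which is the mm10 assembly, and the GENCODE vM21 annotation were used for positions and genes, and chromosomes were limited to the autosomes, X and Y. Coordinates are 1-based. Peaks overlapped if they shared at least 1 bp. Regions were merged over both libraries, and a region with a peak of each counted as shared. A promoter was 1000 bp on either side of the 5' end of a protein-coding gene. For each of 25 gene lists, fixed with the motifs before the data were examined, members with a promoter peak in both libraries were compared with all other protein-coding genes by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over the lists and a threshold of 0.05. Of 334 list entries, 334 were found in the annotation. Distal regions per gene were compared with 10000 seeded random lists matched on the decile of domain length, with a two-sided permutation p and the same adjustment. The p values describe how a list stands among genes of these libraries, because genes are not replicates.

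For 32 motifs written as consensus sequences, exact matches on both strands were found in shared regions, and a match counted as occupied with at least 50% of its bases in a footprint. Occupied shares were compared with those of 20 seeded permutations of each consensus by Fisher's exact test. A second test compared 200 bp windows centred on shared distal regions with windows 1000 bp away that held no peak. Footprints depend on the sequence preference of DNase I, and permuted motifs account for base composition only. Matches and windows are not replicates either.

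Genes were named by a fixed rule: up to 3 members of each list by mean rank of the promoter peak, up to 3 in alphabetical order with no promoter peak in either library, the 20 genes with the most distal regions, the Hox genes by paralogous group, and the 5 strongest shared peaks. An item that the rule names is not reported here. Members outside the rule are marked as chosen after their values were seen. The promoters of genes whose 5' ends lie within 2000 bp of another gene, 3107 genes in all, cannot be assigned to either gene.

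Alternatives covered promoter widths of 500 and 2000 bp, any annotated transcript start, a peak in either library, each library alone, the peaks above the median signal, a 50% reciprocal overlap, equal numbers of peaks, CpG-matched random lists, regions within 50000 bp, matching on promoter peaks, footprints found in both libraries, whole matches, 100 bp windows, permuted motifs in the same windows and GC-matched flanks. The tests of these comparisons and these alternatives were fixed with the lists, and the closing section names the tests and alternatives that were added later. The scripts were tested on simulated data. Of 4000 planted motif matches 4000 were found, of 2000 occupied matches 2000 were found, and a planted overlap of 69.9% was returned as 69.9%. Lists of 15 genes with few promoter peaks were called in 99% of cases, and lists with 3-fold more distal regions in 62%, while unchanged lists passed an unadjusted 0.05 in 1.5% and 0%. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0 and matplotlib 3.10.9. Allele-specific signal of the 2 parental strains was not analysed here.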

Results

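Accessible chromatin was mapped by DNase-seq, in which DNase I cuts open DNA and the cut ends are sequenced, in kidney tissue of female mice aged 4 days. The mice were B6CASTF1/J, the first-generation cross of the C57BL/6J and CAST/EiJ strains. The series held 1 group of 2 libraries, labelled biological replicates 1 and 2, so no condition was compared with another. The questions put to the files were how closely the libraries matched, which kidney cell types left promoter and distal peaks, and which sequence motifs lay in footprints. Replicate 1 held 250423 peaks covering 49.6 Mb and replicate 2 held 216738 peaks covering 41.4 Mb, with a median width of 180 bp in both. Footprints, short stretches protected from cutting, numbered 717738 and 577067, with a median length of 11 bp. Read totals were not given in the files, so no depth was known directly. The scale of the deposited peak signal is not stated, so signals are given on the deposited scale, and the 2 values given for a gene are those of replicate 1 and replicate 2.

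Strong peaks were found in both libraries, and weak peaks often in 1 library alone. Of the peaks of replicate 1, 71.4% were overlapped by a peak of replicate 2 (exact 95% binomial interval 71.2 to 71.6). Of the peaks of replicate 2, 82.6% were overlapped by a peak of replicate 1 (82.4 to 82.7). With the peaks of 1 library moved to random positions these shares were 3.38% and 3.92%. In decile 1 of peak signal, the weakest, 26.7% of replicate 1 and 38.7% of replicate 2 were overlapped, against 99.1% and 99.4% in decile 10, the strongest. The intervals cover counting error only.

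**Figure D1:**
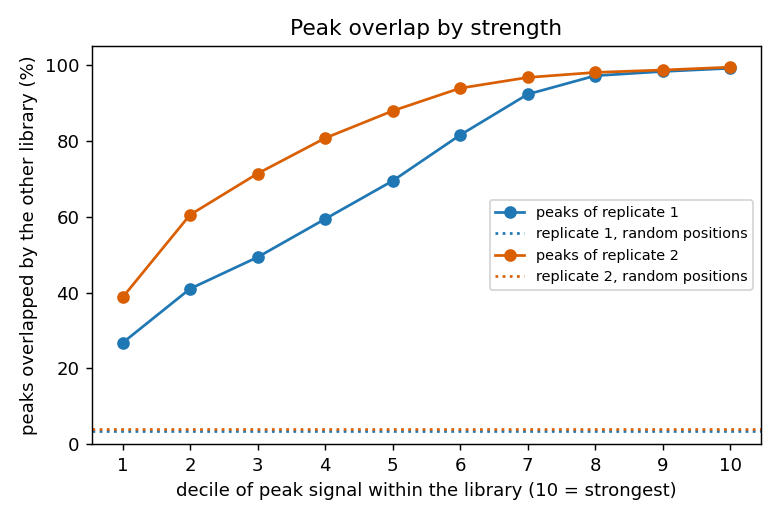
Share of peaks overlapped by the other library (y axis, percent) by decile of peak signal within the library (x axis, 10 the strongest), for replicate 1 (blue) and replicate 2 (orange), with the share at random positions as dotted lines. The share rose from 26.7% to 99.1% in replicate 1 and from 38.7% to 99.4% in replicate 2.

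Merging the peaks of both libraries gave 282288 regions, of which 174246 (61.7%) held a peak of both. A further 70572 regions were seen in replicate 1 only and 37470 in replicate 2 only. Of the regions seen in 1 library only, 89.0% in replicate 1 and 92.5% in replicate 2 lay below that library's median peak signal. Across the shared regions, which are not independent replicates, the signals of the libraries correlated with Spearman rho 0.94 and, on the log2 scale, Pearson r 0.959. The log2 ratio of replicate 2 over replicate 1 had a median of 0.06 and an SD of 0.50, and 94.9% of shared regions lay within 2-fold of the median ratio. Footprints were shared less often than peaks: 50.5% of those of replicate 1 and 65.5% of those of replicate 2 overlapped a footprint of the other library.

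The strongest shared peaks lay at promoters and at 1 locus on the X chromosome. The top region by mean rank was X:169998261-169998420 on mm10, in an intron of Mid1 (X:169685199-170005736) and upstream of Gm21887, with signals of 76.7 and 73.0. A neighbouring region at X:169997921-169998240 had signals of 66.8 and 66.9. The promoter region of Gm21887 at X:170009841-170010160, chosen after its values were seen, carried 3 evenly spaced copies of 1 sequence, the TFAP2 match GCCCCGAGGC, starting at 170009959, 170010040 and 170010121. Signal in repeated sequence is uncertain. The other strongest regions were the promoters of Dynlt1b, a dynein light chain (17:6430021-6430180, 73.9 and 65.1), Hjurp, the chaperone of the centromeric histone (1:88277521-88277760, 67.0 and 61.7), Mplkip (13:17694881-17695100, 59.8 and 52.7) and, with the same mean rank, Ankhd1 (18:36560241-36560500, 53.9 and 54.2). The Dynlt1b promoter peak held a GC box, GGGGCGGGGC, at 6430082-6430091, and the Mplkip peak held 2 on the reverse strand, at 17694931-17694940 and 17695006-17695015. All 3 matches lay wholly inside a footprint in both libraries. An ETS match in the Hjurp peak, ACTTCCGGT at 88277614-88277622, lay outside every footprint of both libraries.

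Promoters held more peaks than random positions and most of the strongest ones. Within 1000 bp of the 5' end of a protein-coding gene lay 11.8% of replicate 1 peaks and 13.1% of replicate 2 peaks. Random positions of the same lengths lay there at 1.64% and 1.69%. Exons of protein-coding genes held 7.08% and 6.8%, and introns 39.7% and 38.5%. Stretches between protein-coding genes, which include noncoding genes, held 41.4% and 41.6%, where random positions fell at 57.7% in both. Median peak signal was 2.06 and 1.83 at promoters and 0.341 and 0.442 between protein-coding genes. Of the strongest 1000 peaks, 85.6% and 85.7% lay at promoters. No test was run on these shares.

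The autosomes held 102 and 88.2 peaks per Mb of sequenced bases and the X chromosome 36.2 and 32.7. X density was therefore 35.5% and 37.1% of the autosomal density. The Y chromosome, absent from female mice, held 89 and 51 peaks, or 1.01 and 0.579 per Mb. Their median signal was 0.031 and 0.116, against 0.419 and 0.536 on the autosomes. Of the protein-coding genes, 70.9% of 20780 on the autosomes and 52.7% of 948 on the X chromosome had a promoter peak in both libraries.

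Genes of nephron progenitors, of the early nephron, of collecting duct principal cells and of stroma had promoter peaks in both libraries throughout, while most genes of liver, photoreceptors, erythroid, immune and germ cells did not. Against random lists matched on CpG content only the collecting duct (permutation adjusted p = 0.01, and 0.01 to 0.474 over all settings) and stromal lists (0.005, and 0.005 to 0.0515) lay above and none lay below. Of 21911 protein-coding genes, 15226 (69.5%) had a promoter peak in both libraries. Every member had one among 13 nephron progenitor genes (Fisher's exact test, two-sided, adjusted p = 0.0334 over 25 lists), 11 early nephron genes (0.0447), 12 collecting duct principal cell genes (0.0447) and 15 stromal and mural genes (0.0263). The share was 18.8% of 16 liver genes (Fisher's exact test, adjusted p = 0.00102), 23.1% of 13 photoreceptor genes (0.00943), 25% of 12 erythroid genes (0.0161), 33.3% of 15 immune genes (0.0199) and 37.5% of 16 germ cell genes (0.0307). Genes used by most cells also lay above the rest, at all 16 cell cycle (Fisher's exact test, adjusted p = 0.0199) and all 17 housekeeping genes (0.0176). Hox genes lay above too, with peaks at all 12 of groups 1 to 4 (Fisher's exact test, adjusted p = 0.0447). All 15 of groups 5 to 9 had one as well (Fisher's exact test, adjusted p = 0.0263). Hox genes lie side by side in clusters, so their p values are too small.

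Among nephron progenitor genes the strongest promoter peaks were at Itga8, an integrin of the kidney mesenchyme (signal 9.26 in replicate 1 and 5.35 in replicate 2), Wt1, a transcription factor needed for kidney formation (6.68 and 7.18), and Pax2, a transcription factor of the kidney lineage (5.89 and 6.51). Wt1 lies at 2:105126529-105173616 and Pax2 at 19:44756045-44837871 on mm10. Early nephron genes were led by the Notch receptor gene Notch2 (17.0 and 13.5), the Notch ligand gene Jag1 (12.7 and 10.2) and Pax8 (7.44 and 7.22). In the collecting duct list Hoxb7 (9.2 and 7.85) and the transcription factor gene Tfcp2l1 (8.56 and 5.43) were followed by Wnt11 (2.95 and 1.75). Stromal genes were led by Col1a1 (11.3 and 7.67), Meis1 (8.02 and 9.56) and Pdgfra (7.63 and 5.36). The highest of all lists was the ribosomal protein gene Rplp0 (30.8 and 25.8), with Actb at 26.0 and 20.7 and the cyclin gene Ccne1 at 28.1 and 18.6.

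The remaining kidney lists did not pass the threshold, though the podocyte list lay above in 5 of 10 alternative settings and the endothelial list in 2. Promoter peaks were present at 15 of 16 podocyte genes (Fisher's exact test, adjusted p = 0.0871), 14 of 16 endothelial genes (0.255), 16 of 21 proximal tubule genes (0.76), 9 of 11 distal tubule genes (0.663), 8 of 11 loop of Henle genes (1) and 6 of 9 intercalated cell genes (1). Podocyte genes with high signals included Foxc2 (10.2 and 10.1) and Vegfa (10.6 and 7.91), and Synpo had no peak at its 5' end but one at another annotated start (4.78 and 4.41). Endothelial genes were led by Ehd3 (10.9 and 9.3) and the VEGF receptor gene Kdr (4.97 and 3.62). Proximal tubule genes were led by the endocytic receptor gene Lrp2 (4.72 and 4.2) and the water channel gene Aqp1 (3.15 and 3.54). Kap and Slc22a8 had no promoter peak in either library, and Hnf4a had none at its 5' end but one at another annotated start (1.83 and 2.09). Chosen after their values were seen, Slc12a1, the salt transporter of the loop of Henle, and Slc5a2, a glucose transporter, had a promoter peak in replicate 1 only, with signals of 0.279 for Slc12a1 and 0.391 for Slc5a2.

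Lists of other tissues held some peaks. No promoter peak was found in either library at the liver genes Alb and Apoa1, the adrenal genes Cyp11a1, Cyp11b1 and Cyp11b2, the fat genes Adipoq and Cidec or the muscle genes Myh1, Myh2 and Myh4. The strongest photoreceptor and germ cell promoters were Opn1sw (7.99 and 7.71) and Gdf9 (21.1 and 24.5), and the 5' end of Gdf9 lies within 2000 bp of that of Uqcrq, so its peak is shared. The lists for adrenal steroid synthesis (4 of 11, Fisher's exact test, adjusted p = 0.0749), fat (7 of 12, 0.663), neurons (14 of 16, 0.255) and skeletal muscle (11 of 16, 1) did not pass the threshold, though the adrenal list lay below in 3 of 10 alternative settings and the muscle list in 1. Promoter CpG content went with these shares: 7.03% of genes in the lowest of 10 CpG groups and 99.6% in the highest had a promoter peak in both libraries. The CpG-matched random lists had 92.3% for nephron progenitors, 90.9% for the early nephron, 66.7% for the collecting duct and 60% for stroma. The width of the promoter moved several shares: germ cells had 6.25% at 500 bp and 50% at 2000 bp, photoreceptors 53.8% at 2000 bp, where they did not pass, immune genes 20% at 500 bp, liver 31.2% at 2000 bp and skeletal muscle 31.2% at 500 bp, where it lay below. Of 10 alternative settings, the call was the same in 2 for the early nephron, 3 for Hox groups 1 to 4, 4 for the collecting duct, 5 for nephron progenitors, 7 for stroma and for Hox groups 5 to 9, and 9 for cell cycle and housekeeping genes. It was the same in 5 for germ cells, 8 for immune and photoreceptor genes, and 9 for erythroid and liver genes. With replicate 1 alone, nephron progenitors, collecting duct, Hox groups 1 to 4 and germ cells (Fisher's exact test, adjusted p = 0.0536 for each) and the early nephron (0.0797) did not pass, although the share stayed at 100% in each of these lists but germ cells, at 43.8%. With replicate 2 alone, the early nephron (Fisher's exact test, adjusted p = 0.0684) and germ cells (0.0524) did not pass, and adrenal genes (0.0489) lay below.

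Genes of the early nephron, podocytes, nephron progenitors, stroma and endothelium, and Hox genes of groups 1 to 11, had more distal regions than genes with domains of like length. None of these kidney lists passed when random lists were matched also on having a promoter peak, or with replicate 2 alone. Of 141046 shared regions over 1000 bp from any gene 5' end, each was assigned to the protein-coding gene with the nearest 5' end, which gave a median of 3 per gene. The list median was 27 for the early nephron, against 11 in random lists matched on domain length (permutation adjusted p = 0.024), 19.5 against 8 for podocytes (0.024), 20 against 7 for nephron progenitors (0.0494), 20 against 8 for stroma (0.0333) and 11.5 against 4.5 for endothelium (0.0393). The Hox lists lay above as well, at 6 against 1 for groups 1 to 4 and 5 against 0 for groups 5 to 9. Groups 10 to 11 had 4 against 0. The permutation adjusted p was 0.00167 for each, from 0.0002, the smallest p the 10000 random lists can give. Hox genes lie side by side in clusters, while random lists drew genes from anywhere, so these p values are too small. No list lay below, and proximal tubule (7 against 4, permutation adjusted p = 0.281), loop of Henle (10 against 6, 0.611), distal tubule (6 against 4, 0.765), collecting duct (5.5 against 3.5, 0.527) and intercalated cells (8 against 4, 0.5) did not pass.

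Within these lists, chosen after their values were seen, Sall1 had 88 distal regions, Six2, the marker of nephron progenitors, 27, Cdh5, the endothelial cadherin, 62, and Tcf21 46. Pax2 had 46, Jag1 47 and Meis1 88. Other members had few, such as Wt1 with 7, Foxc2 with 6 and Eng with 5. The range was 1 to 88 for nephron progenitors, 8 to 97 for the early nephron, 1 to 46 for podocytes, 2 to 62 for endothelium and 4 to 88 for stroma. Lists of other tissues did not pass: neurons 7.5 against 5.5 (permutation adjusted p = 0.687), liver 2.5 against 3 (0.896), skeletal muscle 3 against 2.5 (0.913), photoreceptors 4 against 2 (0.643), germ cells 3 against 2 (0.59), adrenal 2 against 3 (0.868), fat 6.5 against 3.5 (0.492), immune 3 against 2 (0.687) and erythroid 2 against 1 (0.697). Cell cycle genes (1.5 against 2, permutation adjusted p = 0.784), housekeeping genes (3 against 2, 0.687) and Hox groups 12 to 13 (2.5 against 1.5, 0.687) did not pass either. With regions within 50000 bp of the 5' end, however, these lists lay above too, at 14 against 7 for cell cycle genes, 12 against 7 for housekeeping genes and 21.5 against 7.5 for Hox groups 12 to 13. The excess was therefore not limited to kidney lists and the other Hox groups. Of 6 alternative settings, the call was the same in 1 for endothelium and 2 for nephron progenitors and stroma. It was the same in 4 for the early nephron and podocytes and 6 for each of the 3 Hox lists above. Neighbouring Hox genes are not independent, and within 50000 bp they count many of the same regions. With lists matched also on having a promoter peak, none of the 5 kidney lists passed, at 27 against 13 for the early nephron, 19.5 against 10 for podocytes, 20 against 10 for nephron progenitors and for stroma, and 11.5 against 5.5 for endothelium. With replicate 2 alone they did not pass either (permutation adjusted p = 0.0558 for the early nephron, podocytes and stroma, 0.0564 for endothelium and 0.0656 for nephron progenitors), at 31 against 14, 22 against 10.5, 24 against 11, 13.5 against 6 and 25 against 10. With replicate 1 alone, endothelium and stroma did not pass (permutation adjusted p = 0.059 for both), while housekeeping genes (8 against 3) and Hox groups 12 to 13 (10.5 against 2) did. In that setting the early nephron median was 43 against 16, nephron progenitors 30 against 12, and Hox groups 1 to 4, 5 to 9 and 10 to 11 had 10.5 against 1.5, 8 against 1 and 6.5 against 0.5.

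**Figure D2:**
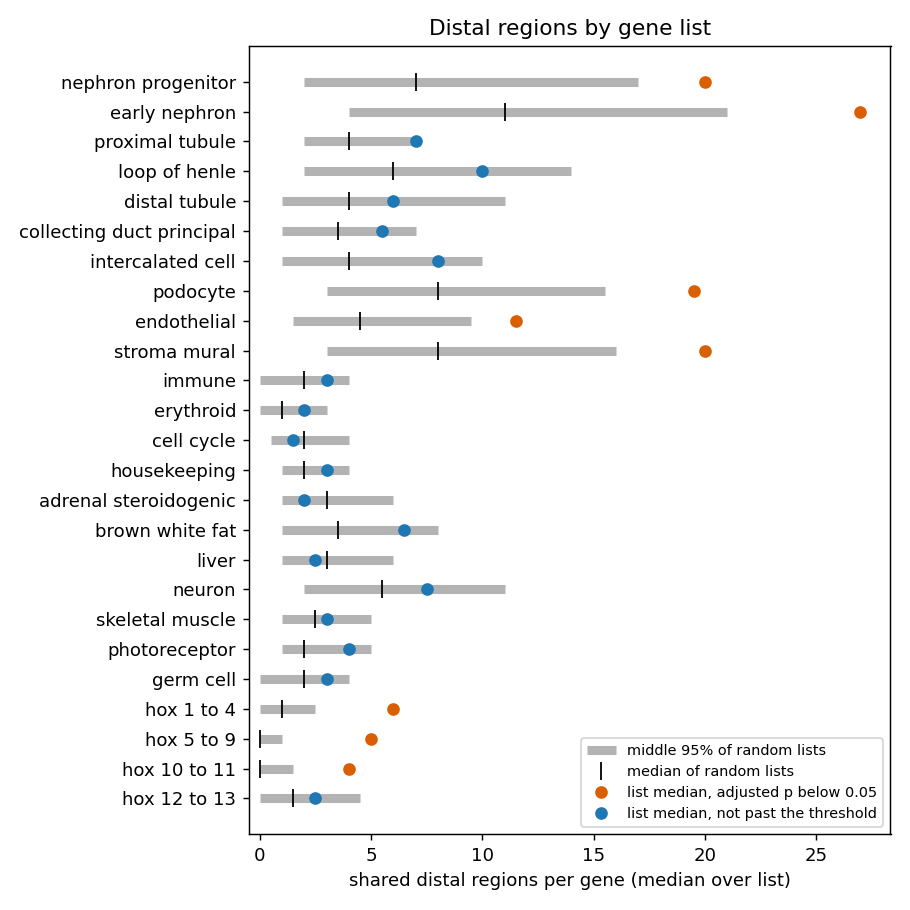
Median number of shared distal regions per gene (x axis) for each of the 25 gene lists (y axis), in orange where the adjusted permutation p was below 0.05 and in blue elsewhere, with the median (black tick) and the middle 95% (grey bar) of 10000 random lists matched on domain length. The early nephron list stood at 27 against 11.

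The 20 genes with the most distal regions had between 89 and 139 each. Zfp608 had 139 over a domain of 1269 kb, the focal adhesion gene Tns1 129 over 555 kb, Lrmda 122, the nuclear receptor gene Nr2f2 121, Zmiz1 119, Adgrl2 114, Bcor, a corepressor on the X chromosome, 113, and Zfp36l1 110. Gm10295 had 98, Galnt17, Maf and Sox9 97 each, Zfp36l2 96, Tns3 94, and Rbfox1 and Tle3 93 each. Myc had 91, Arid1b and Sulf2 90 each, and Smad7 89. A region is counted for the nearest gene and was not tied to it by any measurement.

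Hox genes had their highest promoter signals in paralogous groups 4 to 10, and in groups 12 and 13 all but Hoxc13 were low. In groups 10 to 11, Hoxa10 had signals of 14.5 and 10.4, Hoxd10 10.4 and 11, Hoxa11 2.33 and 3.21, Hoxc11 2.07 and 1.4, and Hoxd11 1.37 and 1.48. In groups 12 to 13, Hoxa13 had 1.3 and 0.879, Hoxb13 0.998 and 0.699, Hoxd12 0.973 and 1.12, Hoxd13 1.23 and 0.729, and Hoxc12 0.595 in replicate 1 and no peak in replicate 2. Hoxc13 stood apart at 5.91 and 6.53. Within groups 1 to 9, high signals were at Hoxa4 (14.3 and 9.83), Hoxa7 (14.4 and 10.8), Hoxa5 (12.2 and 6.74) and Hoxc6 (11.2 and 11.7), while Hoxb1, Hoxb3 and Hoxc4 lay lower at 1.06 and 0.832, 0.797 and 1.22, and 0.815 and 1.3. Hoxc5 and Hoxc10 share 1 peak (21.4 and 15.6), since their annotated 5' ends lie within 2000 bp of each other, as do Hoxd3 and Hoxd4 (4.13 and 4.22). The lists for groups 10 to 11 (6 of 6, Fisher's exact test, adjusted p = 0.26) and 12 to 13 (5 of 6, 0.766) did not pass the threshold for promoter peaks. A list of 6 genes could not lie above, since 6 of 6 gave an unadjusted p of 0.187 (Fisher's exact test).

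**Figure D3:**
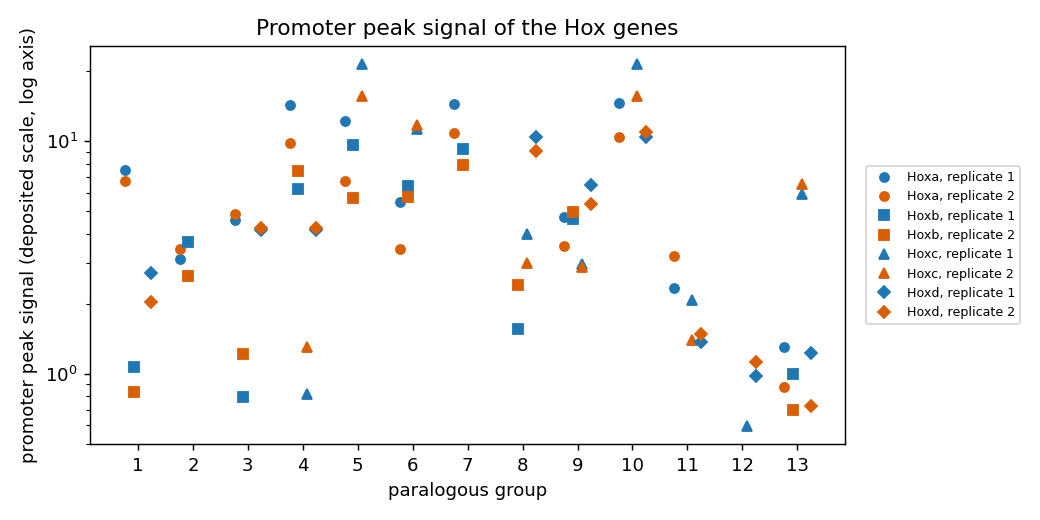
Promoter peak signal of each Hox gene (y axis, deposited scale, log axis) by paralogous group (x axis), for replicate 1 (blue) and replicate 2 (orange), with a marker shape for each cluster; a gene with no peak in a library has no point there. Hoxa13, Hoxb13 and Hoxd13 lie between 0.699 and 1.3, and Hoxc13 lies at 5.91 and 6.53.

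Footprints covered matches of CTCF and of several kidney and promoter factors far more often than matches of the same letters in permuted order. Inside shared regions, 94.8% of 6734 CTCF matches in replicate 1 and 91.7% in replicate 2 lay in a footprint, against 30.7% and 24.7% of matches of permuted motifs. For the full site, shared by the proximal tubule factor HNF4 and by PPAR, the shares were 57.8% and 61.7% of 128 matches against 16.2% and 12.3%. The shorter HNF4 site was in footprints less often, at 27.3% and 23.8% of 1065 matches against 14.8% and 12.3%. The shorter site GTTAATNATT of the epithelial factor HNF1 lay in footprints at 30.6% and 33.7% of 975 matches against 12.1% and 8.18%. Matches of NFI reached 86.2% and 82.8% of 325 against 19.3% and 16.6%, and NRF1 93.7% and 92.7% of 507 against 35.1% and 29.3%. Of 71 RFX matches, 78.9% and 78.9% lay in footprints against 16.7% in both libraries, but its permutations gave only 6 matches.

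Of 32 motifs, 21 lay above their permutations in both libraries and 3 below (Fisher's exact test per motif, two-sided, Benjamini-Hochberg adjusted p below 0.05 in each library). The 3 below were FOX (5.57% and 4.24% against 10.4% and 8%), the Six2 motif TCAGGTTTC (10.5% and 6.9% against 15.5% and 13.4%) and TFAP2 (36.7% and 31.1% against 41.7% and 33.6%). The loop of Henle factor POU3F (13.1% and 10.1% against 12% and 9.29%) and the Six2 motif TGATAYCNNA (12.9% and 10.5% against 12.6% and 10.7%) passed in neither library, nor did PU.1, a myeloid factor, or CRX, a photoreceptor factor. The E-box CAGCTGTT, listed for skeletal muscle, lay above in both libraries (24.1% and 22.9% against 16.4% and 13.9%). Footprint shares therefore did not set kidney motifs apart from all motifs of other tissues. AP-1 (11.4% against 12.4%) and GATA (9.86% against 11.7%) lay below in replicate 1 only, and MEF2 (10.9% against 8.22%) lay above in replicate 2 only. All 12 REST matches lay in footprints, but the permutations gave no match to set beside them. Matches are not replicates, so these p values say how matches differ within each library.

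**Figure D4:**
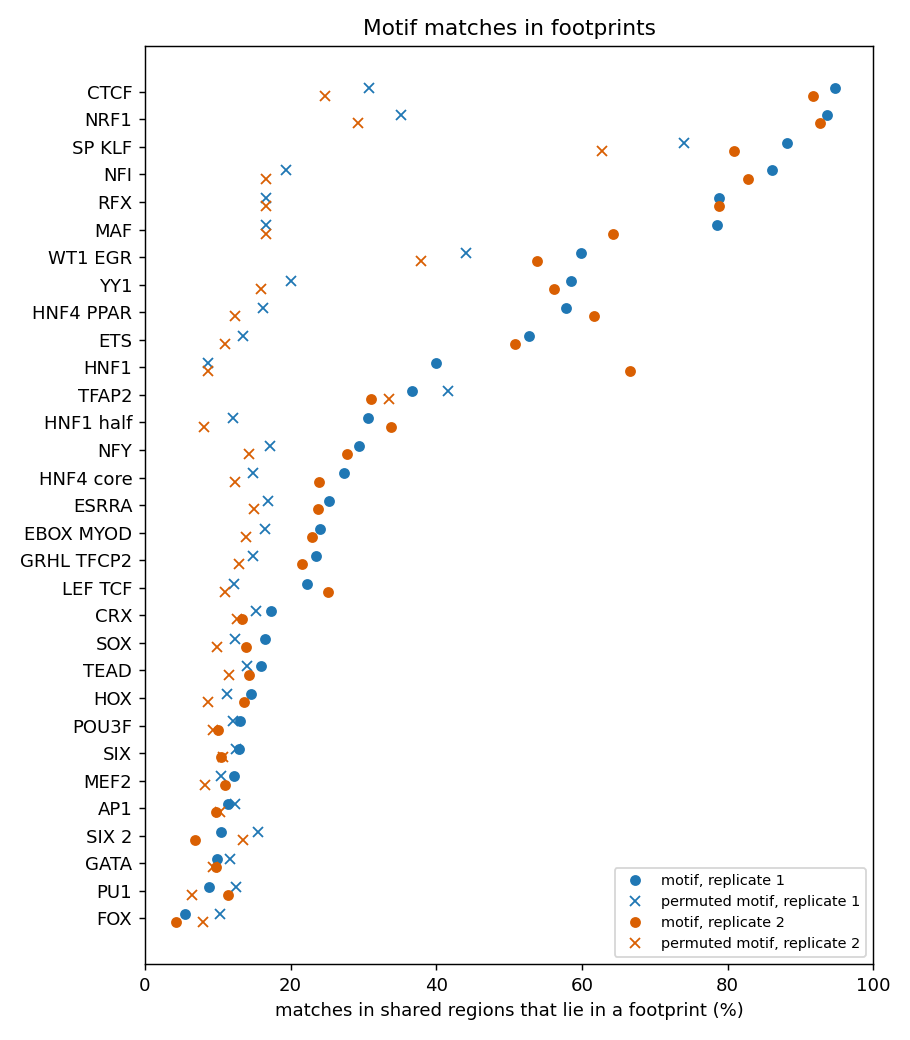
Share of motif matches in shared regions that lie in a footprint (x axis, percent) for each motif (y axis), as dots for the motif and crosses for its permutations, in blue for replicate 1 and orange for replicate 2; REST, whose permutations gave no match, is left out. CTCF stands at 94.8% and 91.7% and FOX at 5.57% and 4.24%.

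Centres of shared distal regions held CTCF, NFI, HNF1 and TEAD matches more often than flanking sequence. In 200 bp windows CTCF matches were present in 4.28% of 141046 centres and 0.054% of 242618 flank windows, a ratio of 79.3. The ratio was 33.8 for NFI and 3.34 for the shorter HNF1 site. It was 2.93 for the full site of HNF4 and PPAR and 2.26 for the shorter HNF4 site. TEAD, in 6.39% of centres, had 2.01, and AP-1, in 5.25%, had 1.55. The E-box CAGCTGTT, listed for skeletal muscle, had a ratio of 3.17 and the myeloid motif of PU.1 had 4.8. The photoreceptor motif of CRX had 0.891. Of the Six2 motifs, TGATAYCNNA had 0.509 and TCAGGTTTC 1.64. These ratios therefore did not set kidney motifs apart from motifs of other tissues. The motif of GRHL and TFCP2, listed for the collecting duct, had a ratio of 2.88 against flanks. Against permuted motifs in the same windows its ratio was 0.166. This motif reads the same on both strands, so it had fewer sequences to match than most of its permutations. That lowers the ratio by an amount that was not measured and may not account for all of it. The motifs of NFI and AP-1 also read the same on both strands. The ratio against permuted motifs was 154 for CTCF, 8.44 for NFI, 4.4 for the shorter HNF1 site and 15.1 for the full HNF4 and PPAR site. It was 4.48 for TEAD, 1.9 for AP-1, 4.77 for the E-box and 0.818 for WT1 and EGR. Of the 32 motifs, 25 lay above the flanks and 6 below (Fisher's exact test, two-sided, adjusted p at most 0.0294), and MEF2 passed neither way (ratio 1.08, adjusted p = 0.15). Centres had a median GC content of 52% and flanks 45%, and with flanks matched on GC content the ratio of HOX went from 0.896 to 1.7, that of POU3F from 0.516 to 1.04, that of MEF2 from 1.08 to 2.43, which passed, and that of the shorter HNF1 site from 3.34 to 10.9. The ratio fell from 11.5 to 3.91 for the GC box, from 5.45 to 2.75 for WT1 and EGR, from 5.43 to 2.85 for NRF1 and from 2.44 to 1.28 for TFAP2, and YY1 and REST no longer passed.

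Distal regions were also set beside the other shared regions. The log2 ratio of the share in distal centres over the share in other shared regions was 1.41 for CTCF, 1.66 for NFI, 1.12 for TEAD and 1.10 for the shorter HNF1 site. It was -4.39 for YY1, -3.17 for NRF1, -2.74 for the GC box and -2.61 for ETS. These ratios were not tested.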

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

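The tests of chance calls were chosen after the overlap between the libraries was seen. Signal outside the peaks was seen as footprints that overlapped no peak of their own library, which numbered 129089 in replicate 1 (18.0% of its footprints) and 88747 in replicate 2 (15.4%). A footprint of the other library overlapped 43.1% of those of replicate 1 and 68.4% of those of replicate 2, against 52.1% and 64.9% of the footprints inside peaks. Set beside the same footprints moved by their width plus 10 bp to places still outside peaks, the share was 41.2% against 15.9% in replicate 1 and 67.1% against 28.4% in replicate 2, a ratio of at least 2.36. The ratio was at least 2.22 on each of the 21 chromosomes in both libraries. It passed the bound set against chance calls as the cause of all of them. It stayed below the higher bound set against chance calls. Moves into a peak were dropped, so the moved places lay farther from peaks. The sequence preference of DNase I was not matched at the moved places. The comparison therefore cannot exclude chance calls. A candidate explanation is that peak borders were drawn narrower than the accessible stretch, since at least 70.6% lay within 100 bp of a peak of the same library (70.6% and 76.6%). The footprints farther away were not explained. The design has no second group, so no biological explanation was tested.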

How the results depend on the processing

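The shorter deposited peak list and the removal of genes that share a promoter were chosen after seeing the data, except that the shorter list was planned for overlap; the cause of each change was not tested unless stated. Overlap of replicate 1 and replicate 2 peaks was 61.6% and 71.2% at 50% reciprocal overlap, 80.5% and 92.6% for peaks above the median signal, 77.9% and 78.0% at equal numbers, and 74.1% and 87.4% with the shorter list. Peaks at promoters made up 12.4% on average, 8.3% and 16.9% at 500 and 2000 bp by construction, 19.9% above the median signal and 17.5% in the shorter list (11.8% to 13.1% with 1 library left out). X density was 36.3% of autosomal density, 25.1% above the median signal and 33.3% in the shorter list (35.5% to 37.1% with 1 library left out). Lists above in promoter peaks fell from 8 to 3 at 2000 bp, 2 with a peak in either library and 2 with CpG matching. They numbered 4 to 7 with 1 library left out (4 without replicate 2) and rose to 9 without genes that share a promoter. Lists below went from 5 to 3 at 2000 bp and 0 with CpG matching. They rose to 6 at 500 bp, above the median signal and in the shorter list. With CpG matching, several lists already at 100% could not lie above. Lists above in distal regions went from 8 to 5 above the median signal, 3 when matched on promoter peaks and 3 to 8 with 1 library left out (3, all Hox lists, without replicate 1; without replicate 2, endothelium and stroma were lost and housekeeping and Hox groups 12 to 13 gained). They numbered 6 with the shorter list and 11 within 50000 bp, where cell cycle, housekeeping and Hox groups 12 to 13 were gained. Motifs below in footprints went from 3 to 5 with footprints found in both libraries and 3 to 5 with 1 library left out (5 without replicate 2). Against permuted motifs, the call reversed for GRHL and TFCP2 (ratio 0.166), WT1 and EGR (0.818) and SOX (0.969), which went below. It reversed for HOX (1.37), POU3F (1.34) and ESRRA (3.04), which went above, and for HOX also with GC-matched flanks (1.7). The GRHL and TFCP2 motif reads the same on both strands, which lowers its ratio against permutations by an amount that was not measured. The lists called for promoter peaks kept their call in 85 of 130 alternatives and those called for distal regions in 31 of 48. Over all single lists and motifs, 72 alternatives lost a call, 23 gained one and 7 reversed one. A further 576 stayed on the same side of the threshold, many with no call in either. REST has no footprint value because its permutations gave no match. It has no enrichment ratio where its control windows held 0 matches, so its lost call with GC-matched flanks is not counted here. No paired analysis was possible because there is 1 group. The unknown depth limits what can be said of weak peaks, and a missing weak peak was not detectable here, not shown absent.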

Other observations

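The tests on motifs by gene list, on library differences by gene list and on the Y chromosome were chosen after the data were seen. Distal regions assigned to early nephron genes carried the shorter HNF1 site GTTAATNATT more often than other distal regions: 10 of 372 (2.69%) against 0.525%, at 6 of 11 genes (Fisher's exact test, adjusted p = 0.00597 over 320 pairs of list and motif). The same regions carried CTCF matches less often, 2 of 372 (0.538%) against 4.29% (exact test, adjusted p = 0.00597). No other pair passed. The next were WT1 and EGR in distal tubule regions (6.25% against 1.07%, exact test, adjusted p = 0.0666) and GATA in endothelial regions (3.63% against 1.14%, 0.193). Regions of 1 gene are not independent, so these p values are too small.

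No gene list differed between the libraries past the threshold. The median log2 ratio of promoter signal, replicate 2 over replicate 1, had its lowest p against random lists matched on signal for Hox groups 1 to 4, at 0.03 against -0.30 (permutation p = 0.0052, adjusted p = 0.109 over the lists with at least 5 members). Endothelial (0.00 against -0.27) and podocyte genes (-0.07 against -0.30) had the next lowest p, both with a permutation adjusted p of 0.185, shared with further lists.

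Promoter peaks on the X chromosome were weaker than on the autosomes. Their median signal was 3.27 in replicate 1 and 3.03 in replicate 2 against 8.18 and 6.55, a log2 ratio of -1.32 and -1.11. Against autosomal genes matched on CpG decile the ratio was -0.83 on average over the libraries, with ranges over 1000 draws of -1.14 to -0.72 and -0.93 to -0.49. The values of both libraries, -0.93 and -0.74, lay past the bound set beforehand against lower CpG content as the cause, but the range of replicate 2 narrowly failed to clear it, so that explanation was not excluded. A candidate explanation from the sex of the animals is that 1 of the 2 X copies is inactive in each cell. Ddx3x, Eif2s3x and Kdm5c, known to be active on both copies, had a median promoter signal at the 98.6 and 96 percentile of 500 X promoters (14.5 and 12.4). Of the 3, Eif2s3x (9.44 and 8.47) lay below the level that had been set for their median (9.75 and 9.24). Kdm6a, another such gene and left out because its value had been seen, had 43.1 and 52.5. The X promoters they were ranked among were not matched on CpG content or breadth of use. The housekeeping list had median signals of 12.4 and 13.1, so strong promoters alone could give such a rank. The rank therefore cannot decide on X inactivation. With 3 genes, no male library and no allele-specific signal used here, an inactive X copy stays a hypothesis.

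Peaks on the Y chromosome fell into 106 regions. Male tissue in the libraries was argued against by the promoters of Ddx3y, Kdm5d, Eif2s3y and Uty, of which 0 of 4 had a peak in either library. Reads from repeated sequence placed on the Y are a candidate explanation. Of the Y regions, 72.6% had at least 50% of their bases in soft-masked repeats, against 6.6% of autosomal regions. Fisher's exact test gave p = 1.77e-66 over regions, which are not replicates. The repeat share of the whole Y was not measured, and a high share could hold for any positions on it. The comparison therefore cannot decide on this explanation. Repeats do not cover the strongest Y regions, which lie near Mid1-ps1. The strongest, Y:90744521-90744820, with signals of 9.18 and 6.2, had 10.3% of its bases soft-masked. No explanation was tested for it. No biological explanation was tested.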
